A study of Mus musculus with 10 samples.

How the data were processed

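The series holds 10 arrays, 5 from untreated mice and 5 from mice given rapamycin. RNA came from sorted B220-negative, Blimp1-positive plasma cells of bone marrow, and was labelled with biotin using an Affymetrix kit, per the labels' protocols. The design text gives 5 mice per group, so that p-values measure the spread between mice. Groups and replicate numbers were taken from the sample titles. No label used here gives a dose, a duration, a sex, a batch or a scan date, so no batch could be tested.

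The values deposited by the authors are on the log2 scale and were made with RMA, per the submitters' processing notes, a method that corrects background, normalizes between arrays by quantiles and summarises probes. The version of RMA and the level of summary were not given in the sources used here. The range and near-equal quartiles of the arrays showed that the values were already normalized and logged, and they were tested as deposited. Quantile normalization sets the arrays to a common distribution, so that a shift of all transcripts in a direction is not seen. The whole value table has 41345 rows. A second deposited table, named as filtered, has 12280 rows, and all 12280 hold the values of the whole table (tolerance 1e-06). The filter's rule was not given. Among probe sets with 1 gene symbol the rows it kept had a median SD over the arrays of 0.19 and those it left out 0.12. Spread alone was not the rule, since the smallest SD kept was 0.10 and the largest left out was 2.86. The latter was that of the X-linked transcript Xist, which the filtered table therefore lacks. The whole table was used for the main results and the filtered one as an alternative.

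Probe sets were named from the platform annotation supplied with the data. It gave 1 gene symbol for 23521 probe sets and several for 1820, and 16004 were unnamed here. Of the probe sets with 1 symbol, 23328 matched NCBI's gene table of assembly GRCm38.p6, which changed 0 symbols and supplied the chromosome and gene type. The files name no genome build, so no coordinates are given. Genes were represented by the probe set with the highest mean over all 10 arrays, which gave 22180 genes, 1082 of them with several probe sets. Probe sets with several symbols or none were tested apart.

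Genes were compared, rapamycin minus untreated, with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, two-sided, with no covariate, no filter on dim genes and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. Adjusted p-values of single genes are from this fit unless another is named, and standard errors are its moderated ones. Gene lists were tested with camera of the same package at its preset inter-gene correlation of 0.01, adjusted over the 34 lists with at least 5 measured members. Of the 35 lists fixed, covering metabolic, stress and plasma cell programs and markers of other marrow cell types, immunoglobulin constant regions had too few measured members. In all, 1021 of 1143 listed genes were measured. Lists were also tested with an estimated correlation, with fry, which asks whether the genes of a list move on balance in a direction without comparing them with other genes, and with an exact permutation test of the list mean per array.

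The genes named in the text were set by a rule. It took the 12 largest rises and 12 largest falls among called genes, leaving out predicted genes, up to 4 members of each list with the smallest p, and Prdm1, Irf4, Xbp1, Sdc1, Tnfrsf17, Mcl1, Hspa5 and Mtor. Only 6 genes fell, so all were named. Kdm6a, Kdm5c, Ddx3x and the genes that open the other observations were chosen after their values were seen. The design, the lists, the rule and the alternatives were fixed before the data were examined, except for the removal of X- and Y-linked genes and the restriction to protein-coding genes, which were added afterwards.

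Alternatives covered a replicate block, the variance model, array weights, the choice among probe sets, filters on mean and variance, the filtered table, normalization, the threshold and leaving out each array. The fit was tested on simulated data of 22180 genes with the real means, the fit's moderated spreads and noise independent between genes. In these data 100 genes were changed by a log2 value of 0.5 and 100 by 1. It recovered 82% and 100% of them, with 10 false calls, and made 0 calls where no gene was changed. Recovery can be lower on the real arrays, whose spreads vary more between genes and where only 34 genes were called. Camera recovered 2 of 2 shifted lists and called 0 others. In unchanged lists whose members were correlated at 0.1, the preset correlation gave a p under 0.05 in 17 of 50 simulations, and at 0.2 in 27 of 50, so that its p-values are too small for lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.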

Results

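Transcript levels were measured on 10 Affymetrix arrays, each hybridised with RNA of plasma cells from the bone marrow of a separate mouse. The mice carried a GFP reporter at the Blimp1 locus, and the cells had been sorted as B220-negative and Blimp1-positive. Blimp1, the product of Prdm1, is the transcription factor that drives plasma cell differentiation, and B220 is a B cell form of CD45 that plasma cells lose. Untreated mice made up a group of 5 and mice given rapamycin, an inhibitor of mTOR complex 1, a group of 5. The dose and length of treatment were not given in the sources used here. Array medians lay between 4.92 and 4.99 on the log2 scale, and Pearson's r between arrays of a group, across genes, ranged from 0.989 to 0.994. The first principal component carried 19.02% of the variance and had negative scores for all 5 untreated arrays and positive scores for all 5 rapamycin arrays. Rapamycin replicate 4 stood apart, with a score of 22.3 on this component against 4.17 to 8.85 for the other rapamycin arrays. The number of arrays limits the precision of every value that follows, and group values are given as mean ± SD over 5 arrays.

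The comparison asks which transcripts of bone marrow plasma cells differ when mice receive an inhibitor of mTOR. However, untreated arrays were high in Y-linked transcripts and rapamycin arrays in Xist, so rapamycin and sex cannot be told apart for any difference below. With rapamycin, Hspa5, which encodes BiP, the main chaperone of the endoplasmic reticulum, fell from 11.49 ± 0.12 to 10.78 ± 0.25 (SD, n = 5 each). Ccr10, a chemokine receptor that guides plasma cells to mucosal tissues, rose from 7.95 ± 0.21 to 8.87 ± 0.25, and the transcription factor gene Myc rose from 7.29 ± 0.24 to 8.06 ± 0.16. Genes of cytosolic ribosomal proteins and of oxidative phosphorylation were higher as groups, and genes of the amino acid response, of protein folding in the endoplasmic reticulum and cytosol, and of the cell cycle were lower as groups, by about 0.1 on the log2 scale each. These calls were made with a preset correlation and all were lost with an estimated correlation, with adjusted p = 0.0697 for the ribosomal and amino acid lists and adjusted p = 0.579 for the others. Markers of neutrophils were also higher as a group, by 0.15, a call lost in the same way (adjusted p = 0.769 with an estimated correlation). The largest differences among the genes tested were those of sex-linked transcripts. Xist, the noncoding RNA that silences an X chromosome in female cells, rose by 5.41, from 3.83 ± 0.10 to 9.24 ± 0.28, while the Y-linked genes Eif2s3y, Kdm5d and Uty had log2 differences of -4.19, -2.86 and -2.48. The lower mean of each of these genes, between 3.69 and 3.99, lay close to the lower quartile of all values on the arrays, 3.81 to 3.87, so that the differences are lower bounds.

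In all, 28 of 22180 genes were higher and 6 were lower with rapamycin at a Benjamini-Hochberg adjusted p under 0.05 in limma. Of these, 2 of the higher genes lay on the X chromosome and 3 of the lower genes on the Y chromosome, which leaves 26 higher and 3 lower genes on other chromosomes. For all 34 genes the values of the groups did not overlap. Groups without overlap were seen for 2.06% of all genes, and chance gives 0.794%. Only 7 of the 34 changed at least 2-fold, namely the sex-linked Xist, Eif2s3y, Kdm5d and Uty, and Tlcd1, Cpne2 and Rnase2a. The number of higher genes fell to 15 without untreated replicate 3, and to 15 without rapamycin replicate 1.

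**Figure D1:**
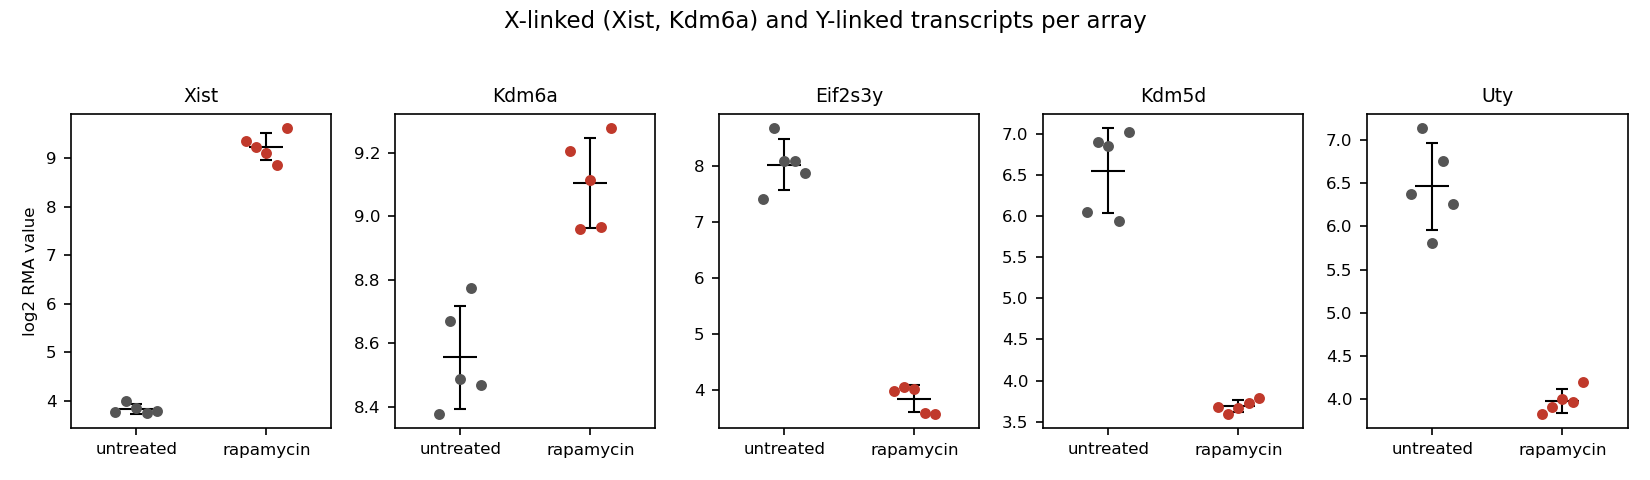
Log2 RMA values of the X-linked transcripts Xist and Kdm6a and the Y-linked transcripts Eif2s3y, Kdm5d and Uty on each array (points), with the mean and SD of the 5 arrays of each group (bar and whiskers). Xist lay near 3.83 in untreated and 9.24 in rapamycin arrays, and each Y-linked transcript was higher on all 5 untreated arrays than on any rapamycin array.

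The sex-linked transcripts parted the groups without exception. On all 5 untreated arrays the mean of Eif2s3y, Kdm5d and Uty was above Xist, and on all 5 rapamycin arrays it was below. In limma, adjusted p was 9.04e-14 for Xist, 1.37e-09 for Eif2s3y, 2.67e-07 for Kdm5d and 1.89e-06 for Uty. Kdm6a, a histone demethylase gene that escapes X inactivation, rose by 0.55 (SE 0.09, adjusted p = 0.0253 in limma); this call was lost without untreated replicate 1, 3 or 5 or rapamycin replicate 1, 3 or 5, with an adjusted p of up to 0.0862. Kdm5c and Ddx3x, which also escape, did not pass the test, with log2 differences of 0.24 and 0.14. Over all 899 X-linked genes tested, the median log2 difference was 0.0133. These transcripts mark the untreated arrays as from male cells and the rapamycin arrays as from female cells, although the labels used here give no sex. Every difference described between the groups is therefore also a difference between Xist-high and Y-high arrays.

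Tlcd1, a regulator of membrane phospholipid composition, rose by 1.30 (SE 0.18, adjusted p = 0.00411 in limma). Its other, dimmer probe set showed a log2 difference of 0.01, and the mean of both probe sets differed by 0.66 with an adjusted p of 0.0536. Cpne2, a calcium-dependent phospholipid-binding protein gene, rose by 1.18, and Lrrc8b, which encodes a subunit of volume-regulated anion channels, rose by 0.83. Ccr10 rose by 0.92 (SE 0.12, adjusted p = 0.0038 in limma), Cd55, whose product protects cells from complement, by 0.69, and Ly6d, a lymphocyte surface antigen gene, by 0.66 (SE 0.07, adjusted p = 5.01e-04). Ifitm3, an interferon-inducible gene that restricts virus entry, rose by 0.78, although its probes can be shared with closely related Ifitm genes. The remaining named genes that rose were Enah, a regulator of actin filaments, by 0.78, Cntnap1, a contactin-associated adhesion protein gene, by 0.74, Myc by 0.77 (SE 0.12, adjusted p = 0.00859), and the kinase gene Dyrk3 by 0.69 (adjusted p = 0.0458 in limma). The Dyrk3 call was lost without untreated replicate 2, 3 or 5 or rapamycin replicate 1, 2, 4 or 5, with an adjusted p of up to 0.112. Ly6d stands on the fixed list of dendritic cell genes and Cd55 on that of mature B cell genes. Neither list passed its test as a group.

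Outside the Y chromosome, 3 genes fell. Hspa5 fell by 0.71 (SE 0.10, adjusted p = 0.0045 in limma). Rnase2a, a gene of the eosinophil-type ribonuclease family whose probes can be shared among its members, fell by 1.28, from 7.84 ± 0.44 to 6.56 ± 0.51 (adjusted p = 0.0347 in limma). Krt36, a hair keratin gene at a low signal of 4.60 ± 0.19 in untreated arrays, fell by 0.51 (adjusted p = 0.0423 in limma). The Rnase2a call was lost without untreated replicate 1, 2 or 3 or rapamycin replicate 2, 3 or 4, with an adjusted p of up to 0.107. The Krt36 call was kept without untreated replicate 1 and lost without any other array, with an adjusted p of up to 0.108.

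**Figure D2:**
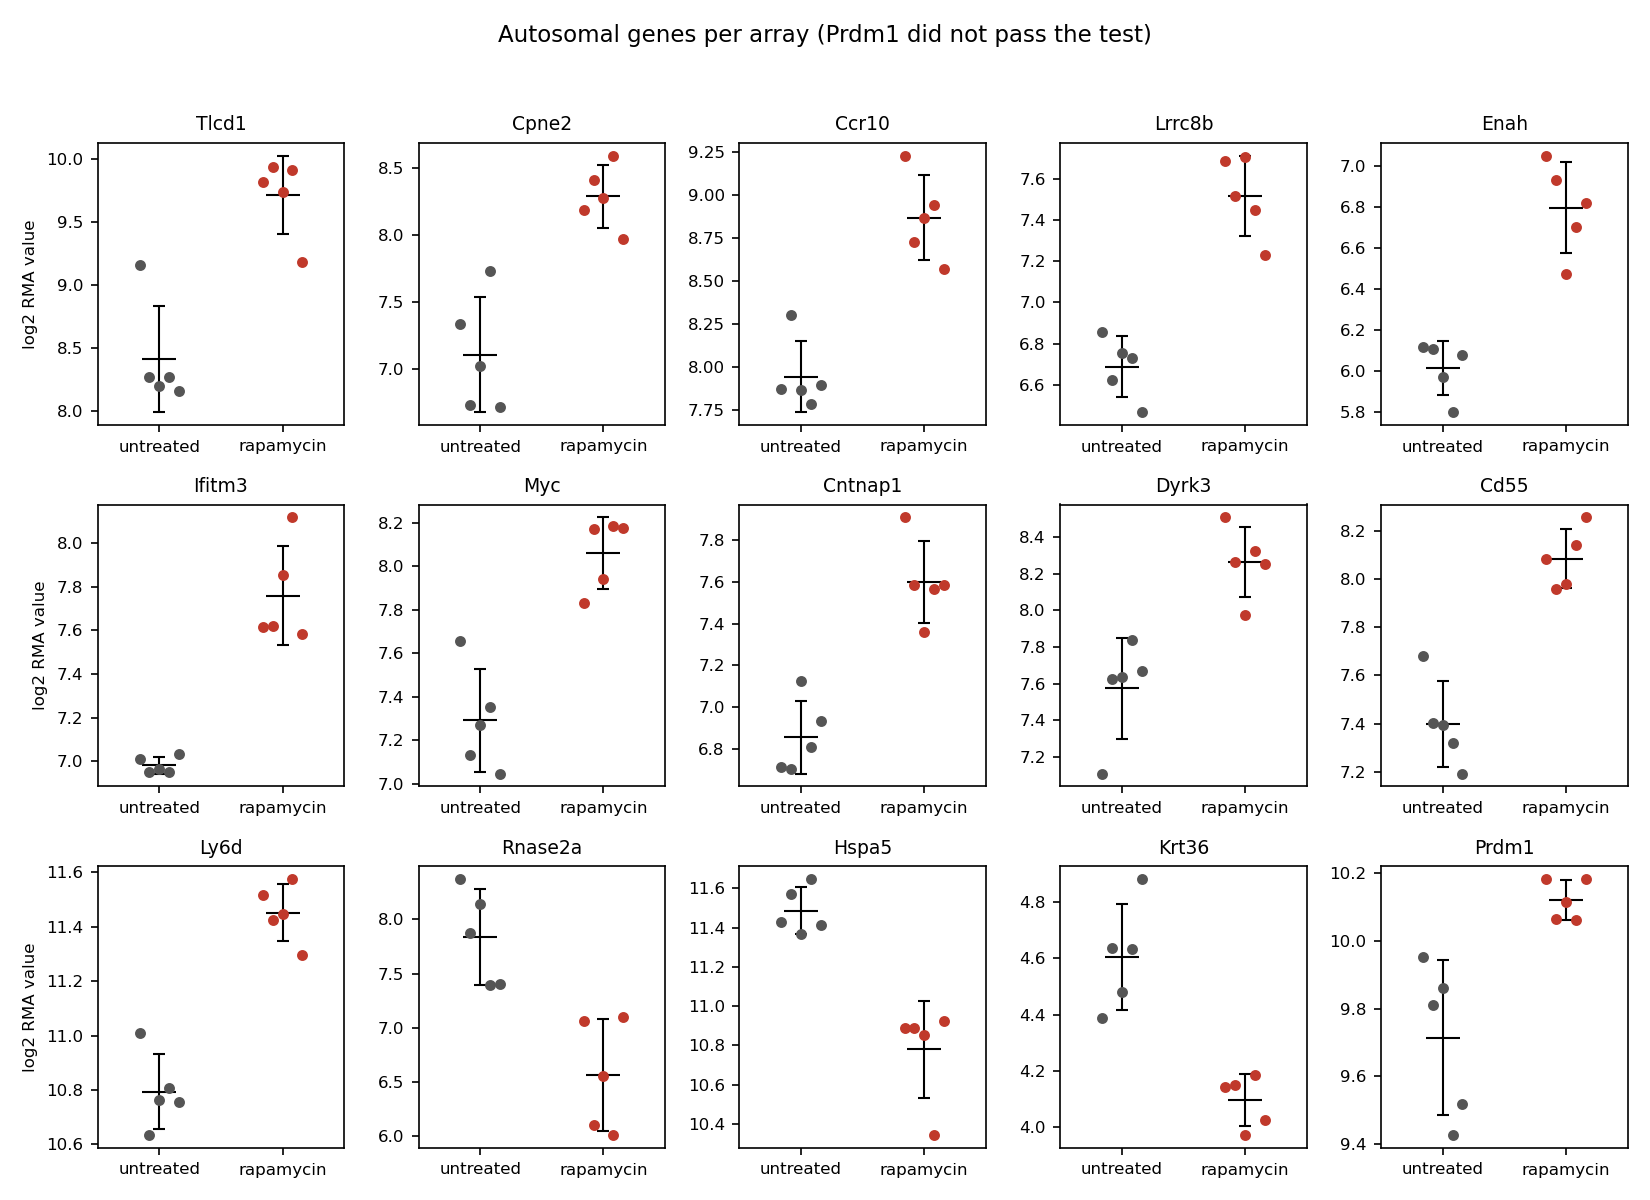
Log2 RMA values per array (points) for 15 genes on autosomes, with the mean and SD of each group of 5 arrays (bar and whiskers). Hspa5 fell from 11.49 to 10.78 and Ccr10 rose from 7.95 to 8.87, with no overlap between the groups; Prdm1, which did not pass the test, is shown for comparison.

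The genes that define plasma cells did not pass the test. Prdm1 had a log2 difference of 0.41 (SE 0.09, adjusted p = 0.117 in limma), with the groups not overlapping. Cells of both groups were sorted as Blimp1-positive, which can limit how far Prdm1 and other plasma cell genes differ between the groups. The differences were 0.11 for Irf4 and 0.02 for Xbp1, transcription factors of the plasma cell program, 0.06 for Sdc1, which encodes the surface proteoglycan CD138, and 0.11 for Tnfrsf17, the survival receptor BCMA. Mcl1, a survival gene of plasma cells, differed by -0.03 and Mtor itself by -0.09. The largest adjusted p of these 6 genes was 0.966 and the smallest was 0.626. Bcl2, another survival gene, differed by 0.50 (adjusted p = 0.0929). On the plasma cell identity list 0 of 35 measured members rose or fell over all genes in limma, 5 were higher and 0 lower at an unadjusted p under 0.05, and 2 rose when adjusted over the list alone, namely Prdm1 and Ly6k, whose log2 difference was 0.81 on its brighter probe set and -0.04 on its dimmer one. The list's mean difference was 0.07 (camera adjusted p = 0.104, and adjusted p = 0.612 with an estimated correlation), and with the preset correlation it passed without rapamycin replicate 4 (adjusted p = 0.00133).

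Antibody transcripts were near the top of the signal range in both groups. The list of immunoglobulin constant regions had only 3 measured members, too few to test as a list. They were Ighm, Ighg3 and Jchain, which is not itself a constant region. Probes of constant regions can be shared among related genes. Ighm was at 13.94 ± 0.07 in untreated and 13.98 ± 0.05 in rapamycin arrays on the brightest of its 7 probe sets. Log2 differences over the 7 ranged from -0.08 to 0.34, both on dimmer probe sets. Another dimmer probe set differed by 0.30 (unadjusted p = 0.0195, adjusted p = 0.413 in limma with every probe set tested). Jchain, which links antibody multimers, was at 13.40 ± 0.04 and 13.45 ± 0.04. Ighg3 was at 13.02 ± 0.21 and 12.69 ± 0.81, and its probe sets disagreed, with log2 differences of -0.33 and 1.34. None of these passed the test in limma.

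The cytosolic ribosomal protein list was higher with rapamycin, by a mean of 0.13 on the log2 scale (camera adjusted p = 8.27e-13, and adjusted p = 0.0697 with an estimated correlation). Of its 59 measured members, 1 rose over all genes, 0 fell and the others did not pass, while 19 rose when adjusted over the list alone. Rpl28, of the large subunit, rose by 0.31 (SE 0.06, adjusted p = 0.0498 in limma), a call that was kept without untreated replicate 1 and lost without any other array (adjusted p of up to 0.142). Log2 differences were 0.26 for Rps3a1, 0.40 for Rps28 and 0.21 for Rpl35, with adjusted p of 0.057, 0.075 and 0.102. Ribosomal protein genes have many processed copies, so that their probes can be shared. Tested on the list mean per array, all 5 rapamycin arrays lay above all 5 untreated arrays (two-sided exact permutation p = 0.00794, the smallest possible, 0.0899 after adjustment over the lists).

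The oxidative phosphorylation list, made up of subunits of the respiratory chain and ATP synthase, was higher by a mean of 0.11 (camera adjusted p = 1.05e-07, and adjusted p = 0.579 with an estimated correlation). Of its 69 measured members 0 rose or fell over all genes in limma, 3 rose when adjusted over the list alone, and 20 were higher and 0 lower at an unadjusted p under 0.05. Subunits of complex I had the smallest p, with log2 differences of 0.26 for Ndufb9, 0.33 for Ndufa3, 0.30 for Ndufa12 and 0.31 for Ndufs8. The exact permutation test of the list mean gave p = 0.00794, or 0.0899 after adjustment.

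The list of ATF4 targets and the amino acid response, genes induced when amino acids run short or translation initiation is blocked, was lower by a mean of -0.10 (camera adjusted p = 5.75e-06, and adjusted p = 0.0697 with an estimated correlation). Of 39 measured members 0 rose or fell over all genes in limma, while 4 fell and 1 rose when adjusted over the list alone, and 2 were higher and 8 lower at an unadjusted p under 0.05. Differences were -0.29 for Slc3a2, the heavy chain of amino acid exchangers, -0.49 for Ddit3, the stress transcription factor CHOP, and -0.32 for the amino acid transporter gene Slc38a2. Ddit4, an inhibitor of mTOR complex 1, went the other way with 0.57 (adjusted p = 0.147).

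The list of the unfolded protein response and chaperones of the endoplasmic reticulum was lower by a mean of -0.09 (camera adjusted p = 5.75e-06, and adjusted p = 0.579 with an estimated correlation). Without rapamycin replicate 4 the mean was -0.06. In untreated replicate 1 the list mean was 10.15, below the rapamycin group mean of 10.16. Hspa5 was the member that fell, of 39 measured, 0 rose, and 6 fell when adjusted over the list alone. Calr, a lectin chaperone gene, differed by -0.26, Herpud1, of the degradation machinery of the endoplasmic reticulum, by -0.23 and the ubiquitin ligase gene Syvn1 by -0.32, with adjusted p of 0.0913, 0.1 and 0.212. The list of heat shock proteins and cytosolic chaperones was lower by -0.11 (camera adjusted p = 0.00119, and adjusted p = 0.579 with an estimated correlation). Its mean in untreated replicate 1, 7.34, lay below all 5 rapamycin arrays, the lowest of which was at 7.37. Of its 29 measured members 0 rose or fell over all genes in limma, 2 fell when adjusted over the list alone, and 0 were higher and 7 lower at an unadjusted p under 0.05. Hspa8, the constitutive HSP70, differed by -0.29, its helper Hsph1 by -0.69 and the co-chaperone gene Chordc1 by -0.28. Hspa1b, whose probes can be shared with its near-identical neighbour, differed by -0.40.

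The cell cycle list was lower by a mean of -0.08 (camera adjusted p = 0.00119, and adjusted p = 0.579 with an estimated correlation). Among 49 measured members 0 rose or fell in limma, over all genes or adjusted over the list alone, and 2 were higher and 4 lower at an unadjusted p under 0.05. Nusap1, a spindle protein gene, differed by -0.49, Cdk1 by -0.32 and Birc5, which lay below the array medians at 3.95 ± 0.18 in untreated arrays, by -0.28, while the thymidine kinase gene Tk1 differed by 0.21. With genes of above-median signal only, the list's adjusted p was 0.0911. The exact permutation test of the list mean gave p = 0.143, or 0.486 after adjustment. Untreated replicate 3, at a list mean of 5.51, lay below the rapamycin group mean of 5.55.

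**Figure D3:**
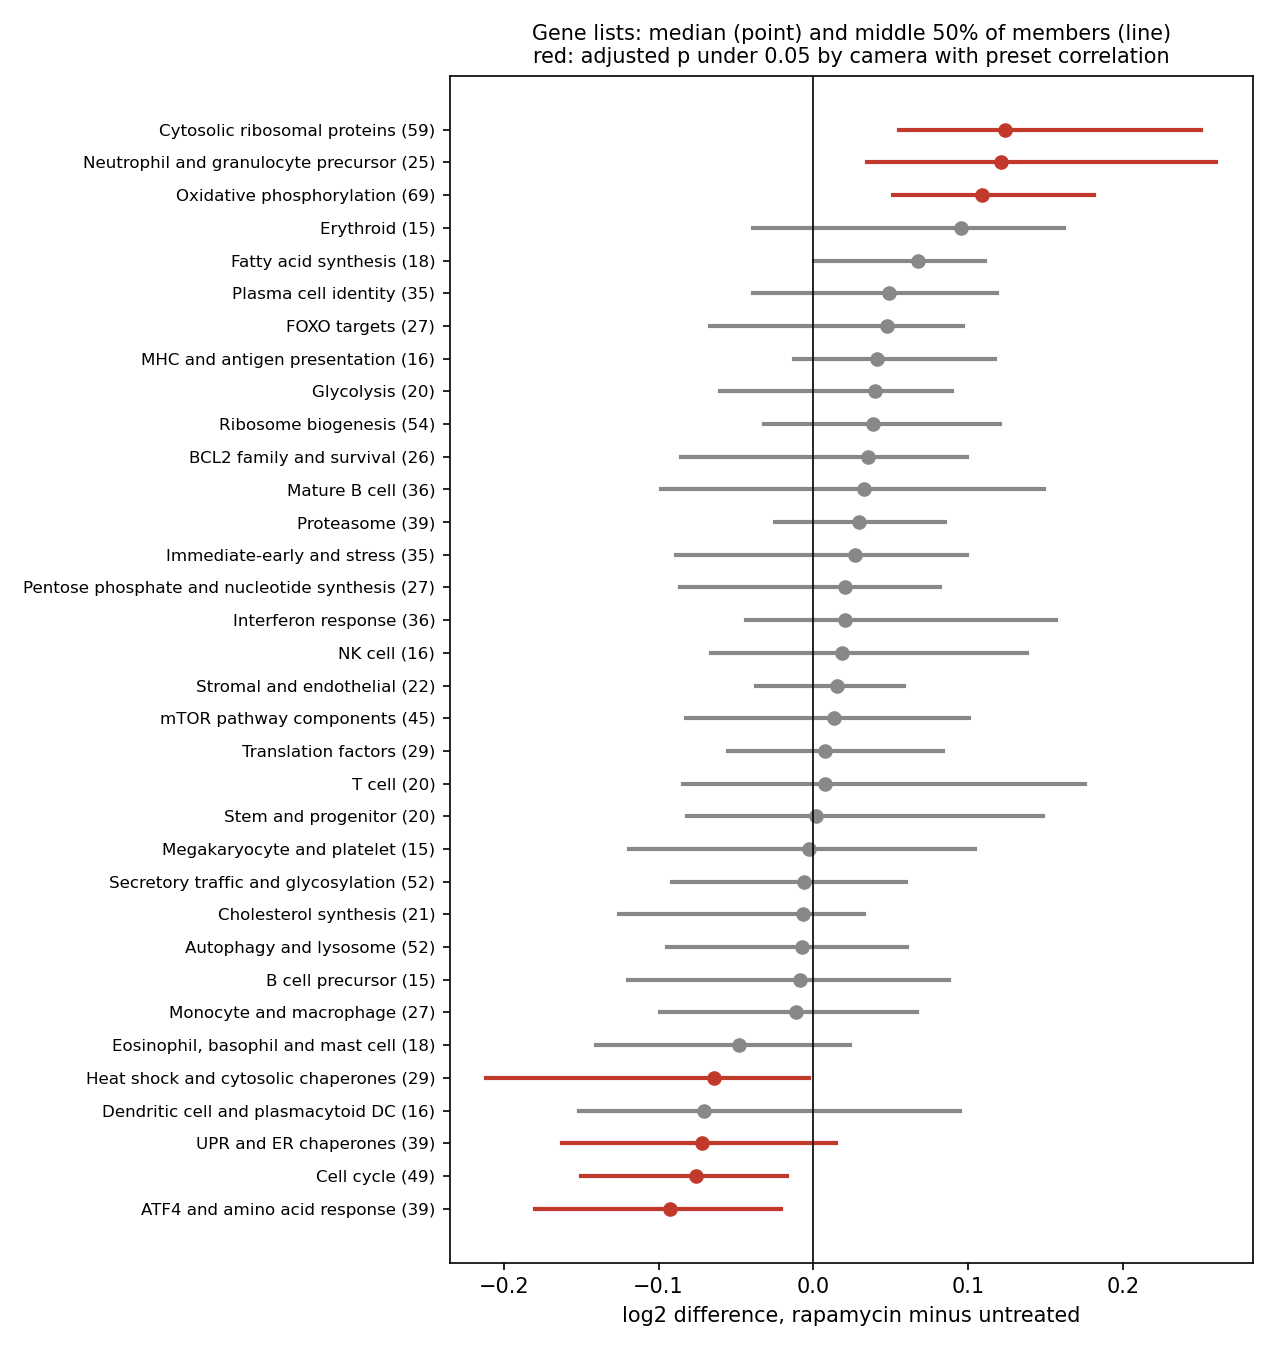
Median log2 difference, rapamycin minus untreated, of the members of each of 34 gene lists (points), with the middle 50% of members (lines) and the number of measured members in brackets. The 7 lists in red had a camera adjusted p under 0.05 with the preset correlation, 3 of them higher and 4 lower; 0 of them passed with an estimated correlation.

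Markers of neutrophils and granulocyte precursors, which the sorting gate should exclude, were higher with rapamycin as a group, although rapamycin replicate 1, at a list mean of 6.18, lay below the untreated mean of 6.22. Their mean difference was 0.15 (camera adjusted p = 0.0216, and adjusted p = 0.769 with an estimated correlation), with 0 of 25 members past the test in limma, over all genes or adjusted over the list alone, and 5 higher and 0 lower at an unadjusted p under 0.05. Differences were 0.35 for the protease gene Prtn3, 0.56 for neutrophil elastase, Elane, 0.38 for Fcnb, below the array medians at 4.81 ± 0.25 in untreated arrays, and 0.26 for Mmp9. The list's call was lost without untreated replicate 3, where the mean was 0.07 (adjusted p = 0.44), and without rapamycin replicate 2, 4 or 5 (adjusted p = 0.0691, 0.129 and 0.0948). Other marker lists did not pass, with camera adjusted p of 0.676 for monocytes and macrophages, 0.693 for eosinophils, basophils and mast cells, 0.629 for erythroid cells, 0.76 for megakaryocytes, 0.881 for T cells, 0.952 for NK cells, 0.942 for dendritic cells, 0.881 for stem and progenitor cells, 0.942 for B cell precursors and 0.942 for stromal and endothelial cells. Members that rose were Ly6c2, on the monocyte list, by 0.45 (adjusted p = 0.0439) and Prg2, on the eosinophil list, by 0.42 (adjusted p = 0.0473 in limma). Ly6d, on the dendritic cell list, rose as well, by 0.66 (adjusted p = 5.01e-04 in limma). Fcer1g of the eosinophil list differed by -0.71 (adjusted p = 0.366). Ly6c2, whose probes can be shared with Ly6c1, and Prg2, the eosinophil major basic protein gene, were abundant in untreated arrays, at 11.22 ± 0.20 and 12.51 ± 0.21. The Ly6c2 call was kept without untreated replicate 2 or 5 and the Prg2 call without untreated replicate 1, 4 or 5; both were lost without any other array, with adjusted p of up to 0.115 and 0.121.

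Further metabolic and B cell lists did not pass. The fatty acid synthesis list differed by a mean of 0.13 (camera adjusted p = 0.144, and adjusted p = 0.579 with an estimated correlation) and with the preset correlation passed without rapamycin replicate 4 (adjusted p = 0.0297). Of 18 measured members 0 rose or fell over all genes in limma and 2 rose when adjusted over the list alone, and 3 were higher and 0 lower at an unadjusted p under 0.05. The desaturase genes Scd1, Fads3 and Fads2 had log2 differences of 0.81, 0.65 and 0.43 and adjusted p of 0.117, 0.0807 and 0.31. The list of secretory traffic and glycosylation differed by -0.02 (camera adjusted p = 0.461, and adjusted p = 0.953 with an estimated correlation) and with the preset correlation passed without untreated replicate 1 (adjusted p = 0.0453). Camera adjusted p was 0.396 for cholesterol synthesis, 0.396 for autophagy and lysosome, 0.543 for ribosome biogenesis, 0.629 for the proteasome, 0.629 for the interferon response, 0.908 for translation factors, 0.942 for glycolysis and 0.989 for the pentose phosphate pathway and nucleotide synthesis. It was 0.916 for components of the mTOR pathway, 0.881 for FOXO targets, 0.81 for immediate-early and stress genes, 0.834 for mature B cell genes, 0.834 for the BCL2 family and 0.881 for antigen presentation. Myc was the only member of the ribosome biogenesis and immediate-early lists that rose. Single members with small p included Ebna1bp2 at 0.40, Hexa at -0.47, Ptprc at -0.35 and Pfkp, a phosphofructokinase gene, at -0.48. Others were the glucose transporter gene Slc2a3 at 0.35, Tpt1 of the translation factor list at 0.36 and the immediate-early gene Egr1 at 0.37. The B cell transcription factor genes Bach2 and Ebf1 differed by -0.39 and 0.36. Casp12, of the BCL2 and survival list, lay below the lower quartile of the arrays at 3.12 ± 0.10 in untreated arrays, and Slpi of the plasma cell list differed by 0.15. Their adjusted p ranged upward from 0.0857, the value of Pfkp.

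**Figure D4:**
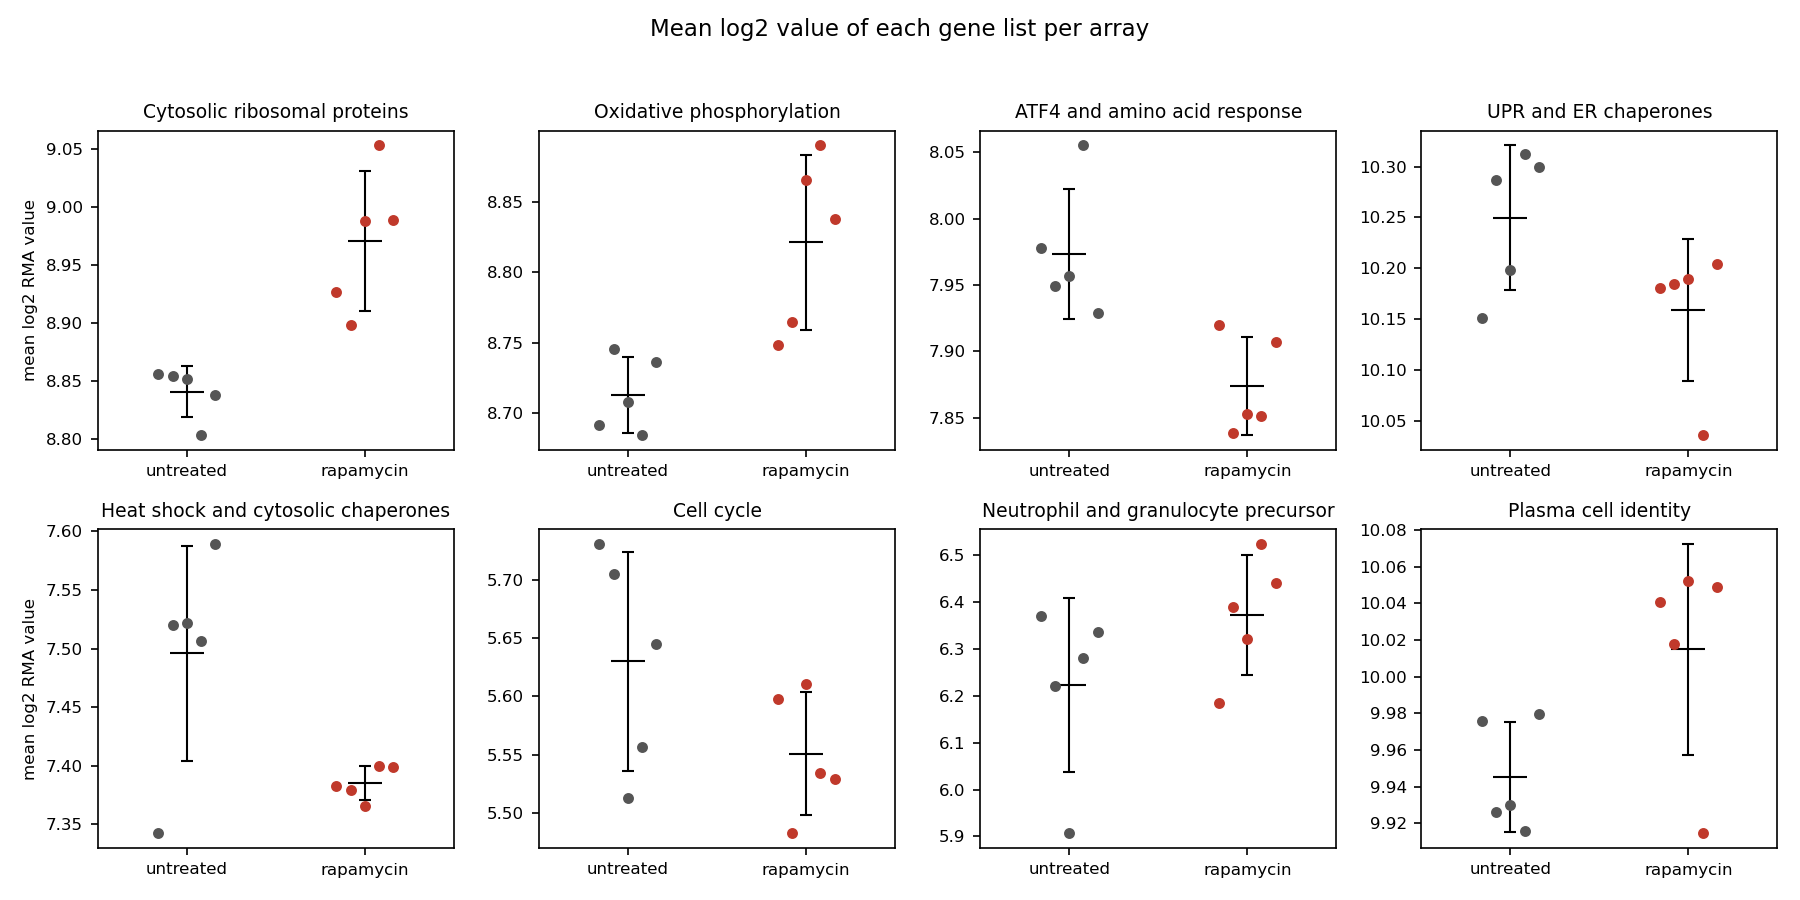
Mean log2 RMA value of the members of 8 gene lists on each array (points), with the mean and SD of each group of 5 arrays (bar and whiskers). The ribosomal protein, oxidative phosphorylation and ATF4 lists do not overlap between the groups, and rapamycin replicate 4 lies lowest for the list of chaperones of the endoplasmic reticulum, at 10.04.

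Leaving out the genes of the X and Y chromosomes, a choice made after seeing the data, gave 22 higher and 3 lower genes. With all genes tested, 26 higher and 3 lower genes lay on other chromosomes, so some of these calls depended on the sex-linked genes being in the fit. The number of lists in each direction stayed the same. All 7 list calls rest on the preset correlation, since 0 lists passed with an estimated correlation and 0 in the exact permutation test after adjustment, and 2 passed with fry.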

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

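All tests of explanations in this part were chosen after the results were seen, whereas the search for outlying arrays was fixed beforehand. That search also covered genes chosen after their values were seen, among them Tmem176b, Atp10a and Sdhaf1.

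X- and Y-linked transcripts part the groups as completely as the treatment does. Xist lay between 3.75 and 4.00 on untreated arrays and between 8.87 and 9.62 on rapamycin arrays. The mean of the 3 Y-linked genes lay between 6.61 and 7.57 and between 3.76 and 3.90. By these transcripts the untreated arrays held RNA of male cells and the rapamycin arrays RNA of female cells. The labels give no sex to check this against. How far sex accounts for the differences of other genes stays open. The 34 changed genes exceeded the highest count of the other splits, 1, in 100 splits of the arrays, as did the 25 left without X and Y genes. Only 1 of 100 splits, the real one, was as large in both cases, which is the smallest share possible. The 34 include X- and Y-linked genes that part the groups completely, so the result for that count could hardly have been otherwise. For the 25 genes left without them, chance is an unlikely account of the number. Whether the 29 called genes on other chromosomes follow rapamycin or sex cannot be told apart, because 0 groups hold both kinds of array. Rapamycin therefore stays open as an explanation beside sex, for these genes and for the gene lists.

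The lists of the unfolded protein response, heat shock and ATF4 were lower, by a mean of -0.10 over lists picked because they were called, and with an estimated correlation these calls were lost (adjusted p = 0.579, 0.579 and 0.0697), as they were in exact permutation tests of each list (adjusted p = 0.36, 0.315 and 0.0899). No single array accounts for the mean shift, of which at least 87.2% was left without any of them, but the list of the unfolded protein response alone went from -0.09 to -0.06 without rapamycin replicate 4. A lower share of plasma cells would lower plasma cell genes. Their list, without members of the unfolded protein response list, was instead higher with rapamycin by 0.0769 (exact p = 0.0317, not adjusted). The full list was higher by 0.07 but did not pass the exact permutation test (p = 0.0556, and 0.315 after adjustment). Nor did it pass camera (adjusted p = 0.104, and 0.612 with an estimated correlation). Neutrophil markers were higher by 0.15 (camera adjusted p = 0.0216, and 0.769 with an estimated correlation), so more RNA from neutrophils stays open. Less handling stress cannot be told apart from the other explanations, since the immediate-early list differed by 0.0341 (exact p = 0.389) with members on both sides of 0 and the heat shock list is part of the pattern. Chance could not be excluded for the number of lists called, since 8 of 100 splits gave as many as the real 7 and the highest other gave 11, and rapamycin and a sex difference stay open as well.

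The lists of cytosolic ribosomal proteins and oxidative phosphorylation were higher together, calls lost with an estimated correlation (adjusted p = 0.0697 and 0.579), and neutrophil markers were higher as a group as well (0.15, adjusted p = 0.769 with an estimated correlation). A shift of all abundant transcripts would move other genes of the same level, yet both medians lay at percentile 100 of 10000 random lists matched on mean level. Short, abundant genes did shift somewhat, with random medians of 0.05 for both lists, but the list medians of 0.12 and 0.11 lay at or above percentile 99.93. These percentiles describe genes on these arrays and are not tests over mice. A response to rapamycin, a sex difference and chance, which 8 of 100 splits leave open for the number of lists, remain possible.

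Arrays that lay far from the others of their group were found in 19 of 236 groups of 5 values, where chance gives 11.8, and 8 of the 19 were in rapamycin replicate 4. In that array Hspa5 was at 10.34 against 10.85 to 10.92 in the other rapamycin arrays, the list of chaperones of the endoplasmic reticulum at 10.04, the plasma cell identity list at 9.91, the B cell precursor list at 5.13, Mtor at 7.54, Rpl35 at 12.21, Hspa1b at 4.62 and Tmem176b at 11.95. Tlcd1 was at 9.16 in untreated replicate 1, against 8.16 to 8.27 in the other untreated arrays, and at 9.18 in rapamycin replicate 5. Ccr10 was at 8.31 in untreated replicate 2, Sdc1 at 10.20 in untreated replicate 5 and Scd1 at 6.46 in untreated replicate 4. Bcl2 was at 10.71 and Sdhaf1 at 8.81 in rapamycin replicate 2, Ighg3 at 11.28 in rapamycin replicate 1 and Atp10a at 5.88 in rapamycin replicate 5. The mean of the ribosome biogenesis list was 7.29 in untreated replicate 1 and that of the glycolysis list 6.82 in untreated replicate 5.

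Among 17824 probe sets outside the gene table, 2 were higher and 1 was lower with rapamycin in limma. The higher ones, unnamed here, had means of 11.25 and 9.56 against 4.46 and 4.42 in untreated arrays, and the lower one, also unnamed here, went from 7.43 to 4.64.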

How the results depend on the processing

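Of 2139 values of named genes under an alternative, 1929 kept their side of the threshold, 166 lost the call, 43 gained it and 1 reversed; of 644 list values, 616, 25, 3 and 0 did. Of those that kept their side, 7 gene values and 31 list values, all uncalled, had the other sign. The reversal was Ighg3, at 1.34 in the filtered table, which holds only the dimmer of its probe sets. The 28 higher genes became 57 with genes of above-median mean, 124 with above-median variance, 71 in the filtered table, 68 at an adjusted p under 0.10 and 15 at a minimum of 1.5-fold. The 6 lower genes became 13, 69, 36 and 24 under the first 4 of these, 12 with array weights, 13 with repeated quantile normalization, 13 with cyclic loess and 3 without X and Y genes (added after the data were seen). Filters test fewer genes and the thresholds set their own counts. With p-values unchanged, a filter at the median could call no more than the 68 higher and 24 lower genes at 0.10. The variance filter's 124 and 69 exceeded this, so fewer tests alone do not account for its counts, and the refit changed the p-values. The cause of the other changes was not tested. Leaving out each array gave 15 to 30 higher and 4 to 9 lower genes, and 2 to 4 higher and 4 to 5 lower lists. With a replicate block there were 14 higher genes, 13 of them among the 28, and 7 lower, and Myc and Cntnap1 had an adjusted p of 0.0684; same-numbered arrays correlated at -0.07 to 0.05 and 2 of 10 arrays correlated best with their own number, so the numbers share no more than a name. Higher lists numbered 0 with an estimated correlation, 1 with fry and 0 by exact permutation, and lower lists 0, 1 and 0, against 3 and 4. Hspa5, Ccr10, Cpne2, Lrrc8b, Enah, Ifitm3, Cd55 and Ly6d passed under all 26 settings run, with Hspa5 between -0.74 and -0.60. Other scalings moved the median difference of all genes from 0.0087 to between -0.0024 and 0.0089. Genes with group means below the array medians, such as Krt36, Birc5, Casp12 and the Y-linked genes with rapamycin, have differences that low signal compresses.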

Other observations

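Genes outside the naming rule also rose, and the following were chosen after their values were seen. Tmem176a and Tmem176b, neighbouring genes of related membrane proteins of intracellular vesicles, rose by 0.50 and 0.52 from levels of 10.60 ± 0.19 and 11.27 ± 0.15 (adjusted p = 0.0253 and 0.00411 in limma). Abca3, a phospholipid transporter gene, rose by 0.60, Atp10a, a phospholipid flippase gene, by 0.45, and the transcriptional regulator genes Runx3 and Arid5b by 0.56 and 0.47. Sdhaf1, an assembly factor of succinate dehydrogenase, rose by 0.52, Cenpq, of the kinetochore, by 0.56, the relaxin-family gene Insl6 by 0.63 and Cnbd2 by 0.38. Dimmer probe sets disagreed, with differences of 0.01 for Sdhaf1 and of -0.09 and 0.04 for Cnbd2, and with the mean of all probe sets both calls were lost, at 0.26 (adjusted p = 0.244) and 0.11 (adjusted p = 0.777). Insl6 and Tmem176b passed without any single array. The others did not: Arid5b was lost without any of the arrays, and Abca3 and Cnbd2 without untreated replicate 3 (adjusted p = 0.0525 and 0.0579). Sdhaf1 was lost without untreated replicate 4 or rapamycin replicate 1 or 2, Tmem176a without untreated replicate 1 or 3 or rapamycin replicate 1, 4 or 5, and Runx3 without untreated replicate 3, 4 or 5 or rapamycin replicate 1, 3, 4 or 5. Atp10a was kept without untreated replicate 1 or rapamycin replicate 5 and Cenpq without untreated replicate 5 or rapamycin replicate 2, and both were lost without any other array.

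The spread between mice of a group was looked at after the data were seen, and the classes of genes below were picked with their values known, so their counts are given as description and not as a test. Only the 11090 genes with a mean above the median of all genes were ranked. Of 19 antibody segment genes among them, 6 (31.6%) were among the 111 genes of largest spread, as were 21 of 167 (12.6%) genes of microRNAs and snoRNAs. The median SD within groups was 0.14 for antibody segments, 0.23 for microRNAs and snoRNAs and 0.16 for the 11090 genes.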
